A study of Mus musculus with 2 samples.

How the data were processed

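Polyadenylated RNA from the left ventricle of 1 wildtype male mouse and 1 male mouse labelled Lamp2 knockout, both of the 129-SvEv strain and aged 10 weeks, was sequenced by the authors. The groups were taken from the genotype labels. STAR and the builds mm10 and GRCm38 are named in the submitters' processing notes, without a version for STAR. The counting tool, the annotation release, the treatment of reads that match several places and the use of strand are not given in the sources used here.

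The authors deposited 1 table of 31920 gene symbols for both libraries. Per the file headers, it holds read counts per gene, which are whole numbers and not normalized. The deposited RPM values equal the deposited count divided by the library's total over all listed genes, times 1000000, with a largest difference of 5e-05. Per the file headers, the table also holds the authors' fold of the knockout-labelled over the wildtype value, left blank for 18680 symbols with fewer than 10 reads in both libraries. Where the wildtype had 0 reads, the authors' fold is printed as 49, so it was not used there. The authors' p-value in the deposited table has no stated method and is not said to be adjusted. Neither the authors' fold nor the authors' p-value was used in any calculation here. Because the mitochondrial share of reads differed between the libraries and each RPM is a share of the total, RPM of all other genes depend on that share.

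Deposited start coordinates count from 0. Of 8973 measured genes whose symbol is in the GENCODE M21 annotation of GRCm38, the start plus 1 matched a transcript start for 44.6% and the start as deposited for 5.85%. Starts are given plus 1. The annotation places Lamp2 from 38401357 to 38456454 on chromosome X.

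With 1 library per group no spread between animals can be estimated, so no test of the genotypes was made. The following were fixed before the data were examined: a gene was measured if it had at least 5 RPM in the higher library, and it was called higher or lower if log2((knockout-labelled RPM + 1)/(wildtype RPM + 1)) was at least 1 in size. The pseudocount of 1 RPM understates differences of low genes. Ratios in the text are of RPM without a pseudocount, with exact conditional binomial (Clopper-Pearson) 95% intervals from the reads. Shares of reads carry exact binomial intervals. Reads without molecular identifiers are not independent molecules, so these intervals and the floors cover counting error only. Ranges called bootstrap ranges are the central 95% of 10000 resamplings of a list's genes; they reflect the spread among those genes, which are not independent, and neither counting error nor the spread between animals. At 8410593 and 8773820 reads, the ratio of a gene near 5 RPM rests on few reads and is known less closely than that of abundant genes.

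Before the data were examined, 42 gene lists with 1138 entries were also fixed, covering autophagy, lysosomes, cardiac stress, contraction and ion channels, matrix, metabolism, stress responses, cell type markers and technical groups. The files held 1116 of the entries. The median log2 ratio of the measured members was set against 10000 random lists of the same size drawn from 20 bins of mean expression. A list stood apart if its median lay outside the central 95% of those medians and it had at least 5 measured members. This describes the 2 libraries and is not a test of the genotypes. The genes named were Lamp2, the 15 with the highest and the 15 with the lowest log2 ratio (provisional gene symbols left out), up to 4 members of each list with the largest log2 ratio in size, and up to 4 abundant members of some lists. Rows named by cDNA clone identifiers are counted but not named. Genes named outside this rule are marked as such, except those given as members shared by lists, as rows not used or in the weighing of causes. Some genes that the rule names are not reported here.

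Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 RPM, minimums of 1 and 20 RPM and no filter, ratios of 1.5 and 3, 3 rescalings, 10 expression bins, the list mean, and an added requirement of an exact binomial test of the reads with Benjamini-Hochberg adjustment. The rescalings divided by the median ratio, by a mean of log ratios with 30% of ratios and 5% of levels trimmed at each end, or by the total without mitochondrial transcripts and the 10 most abundant genes. A correction of log2 ratios for transcript length and GC content, the removal of cDNA clone rows and 3 more gene lists were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

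The rule was tested on simulated counts for this comparison, drawn from the measured means and library sizes with 200 changed genes. It recovered 96% of genes changed 3-fold, called 0% of those changed 1.5-fold and called 0 unchanged genes from counting error alone among 10032 genes. The intervals covered a ratio of 1 for 95.3% of 9832 unchanged genes. With an assumed coefficient of variation between animals of 0.1, 0.2 or 0.3, it called 4, 194 and 1050 unchanged genes. Of random lists of 25 genes, 4.5% stood apart, as the central 95% bound fixes in advance, and of lists shifted by 0.3 on the log2 scale, 86% did. Genes of a real list vary together, so 4.5% is not the rate at which unaffected real lists would stand apart.

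Of the measured rows, 2045 overlap another measured row, 693 of them on the same strand, so some reads may have been counted in more than 1 row. Such genes, and genes with near-identical copies such as ribosomal proteins, are uncertain.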

Results

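The series is titled as a study of cardiomyopathy from loss of LAMP2, a membrane protein of lysosomes, and of impaired autophagy, the pathway that delivers cell contents to lysosomes. Polyadenylated RNA of the left ventricle was sequenced from 2 male mice of the 129-SvEv strain aged 10 weeks. The wildtype group and the group labelled Lamp2 knockout held 1 library each, so no difference has a replicate check. No p-value across genes is given, and the intervals given with ratios and shares of reads cover counting error only. The wildtype library held 8410593 reads assigned to genes and the library labelled Lamp2 knockout held 8773820. At least 10 reads were counted for 12755 genes in the wildtype and 12714 genes in the other library. A count of 3 reads, the most that a gene listed at 0 allows, corresponded to 0.357 and 0.342 reads per 1000000 reads assigned to genes (RPM).

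Lamp2 transcripts were present at similar levels in both libraries. The gene, on the minus strand of chromosome X from 38401361 to 38456455 in the mm10 build, had 990 reads in the wildtype and 986 in the other library. These counts correspond to 118 and 112 RPM, a ratio of 0.955 (95% interval 0.873 to 1.04), which did not differ from 1 beyond counting error on the deposited scale. It did under each rescaling, at 0.882 (0.807 to 0.965) with the median ratio, 0.878 (0.803 to 0.960) with a trimmed mean of log ratios and 0.834 (0.762 to 0.911) with the total without mitochondrial transcripts and the 10 most abundant genes. The labels do not state which part of the gene the allele removes, and a count over the whole gene cannot check a deletion that leaves the remaining transcript in place. The expression of the targeted gene therefore does not check the genotype label, and every direction below refers to the library labelled Lamp2 knockout, called the knockout-labelled library. In the genes near Lamp2 on the X chromosome, 0 of 14 measured members reached a 2-fold difference, and Ube2a, a ubiquitin-conjugating enzyme, and Slc25a5, a mitochondrial nucleotide carrier, had the largest ratios at 1.79 (1.57 to 2.04) and 1.79 (1.49 to 2.16). The median log2 ratio of these neighbours was 0.09, at percentile 38.0 of random gene lists of like expression.

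The comparison of the libraries asked which left ventricle transcripts differed between the Lamp2 genotypes as labelled. Ranked by log2 ratio with a pseudocount of 1 RPM, the largest excess in the knockout-labelled library was in Lcn2, which encodes the iron-carrier-binding acute-phase protein lipocalin 2 (chromosome 2, 32384637 to 32387739). Its level was 184 RPM against 6.90 RPM, a ratio of 26.7 (20.5 to 35.3). Mt2, a metal-binding metallothionein, followed in that ranking at 1093 against 119 RPM (ratio 9.19, 8.61 to 9.81), and the acute-phase protease inhibitor gene Serpina3n stood at 415 against 52.4 RPM. Serpina3n belongs to a cluster of closely similar genes, so its reads may be shared with them. In the same ranking the largest deficits were in Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, at 3.42 against 52.7 RPM (ratio 0.0649, 0.0433 to 0.0940), and in the mitochondrial carrier gene Ucp3 at 6.84 against 83.2 RPM. Rgs2, a regulator of G protein signalling, was at 9.57 against 81.1 RPM, and the α1-adrenergic receptor genes Adra1a and Adra1b had ratios of 0.189 (0.135 to 0.261) and 0.192 (0.143 to 0.255).

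Among the other genes with the highest ratios were the stress-responsive endothelial gene Apold1 at 146 against 18.8 RPM and the calcium-binding protein gene Efhd2 at 424 against 67.8 RPM. The deubiquitinase gene Otud1 was at 219 against 38.6 RPM. Sphk1, which makes sphingosine 1-phosphate, had a ratio of 8.49 (5.39 to 14), and the hormone gene Stc1 a ratio of 9.29 (5.24 to 17.9). Fam46b, Slc10a6 and Syt12 had ratios of 13.0, 7.97 and 5.91. Ratios of S100a9, Olfm2 and Prom1 rested on at most 5 wildtype reads and were 16.9 (6.96 to 53.2), 20.8 (6.80 to 103) and 15.8 (5.89 to 59.8). Among the other genes with the lowest ratios, the phosphatase gene Dusp18 was at 18.7 against 87.2 RPM. Lrrc15, Scd4 and the chemokine gene Ccl2 had ratios of 0.158, 0.139 and 0.120. Gpr22 and B3galt2, at ratios of 0.0599 and 0.114, each lie within another expressed gene on the opposite strand. Ucp3 and Syt12 are also overlapped by opposite-strand rows, and the counting is not stated to use strand, so reads of these 4 genes cannot be told apart from those of their partners.

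**Figure D1:**
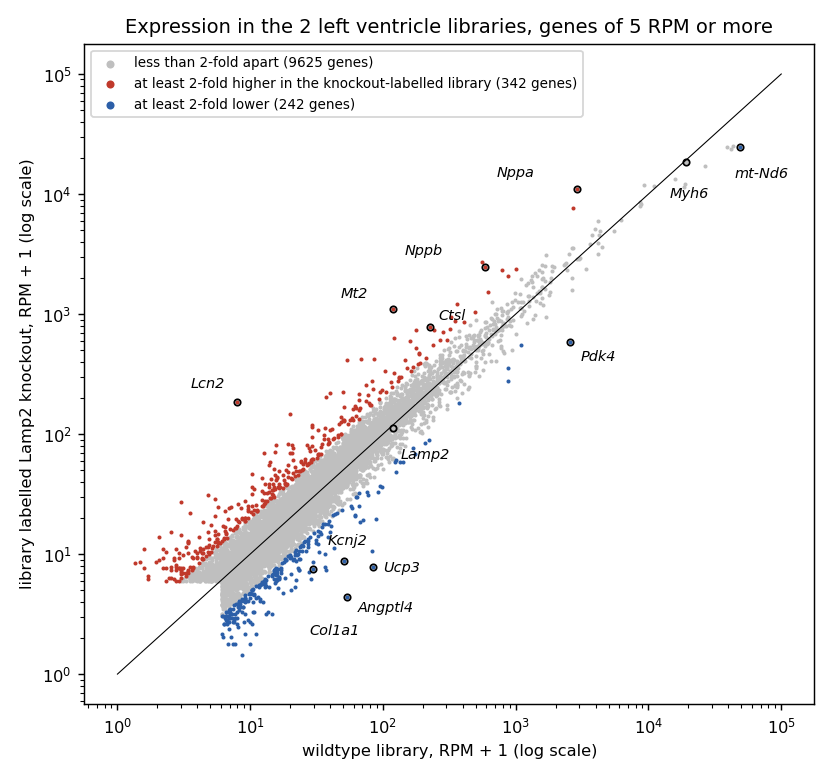
RPM plus 1 in the wildtype library (horizontal, log scale) and the library labelled Lamp2 knockout (vertical, log scale), 1 point per gene with at least 5 RPM in the higher library; the diagonal marks equal values. Lcn2 lies farthest above the diagonal at 184 against 6.90 RPM, Angptl4 lies below it at 3.42 against 52.7 RPM, and Lamp2 lies near it at 112 against 118 RPM.

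In all, 342 of 10209 measured genes were at least 2-fold higher in the knockout-labelled library and 242 were at least 2-fold lower, so 58.6% of these genes were higher. The counting interval of the ratio excluded 1 for each of them, which the 5 RPM minimum and the rule of size ensure at these depths. Within 1.5-fold lay 79.9% of measured genes. The median log2 ratio of all measured genes was 0.11, with quartiles of −0.16 and 0.39. Most measured genes therefore lay above 0 on the deposited scale, and members above 0 in a list are to be read against that. Rescaling turned the balance: the counts were 253 and 316 (44.5% higher) after division by the median ratio, a shift of 0.11 on the log2 scale. They were 249 and 323 (43.5%) after a trimmed mean of log ratios, a shift of 0.12, and 214 and 394 (35.2%) after scaling to the total without mitochondrial transcripts and the 10 most abundant genes, a shift of 0.20. Each rescaling lowers the log2 ratios, by less for genes near the pseudocount, which makes positive list medians smaller and negative ones larger in size. In simulations with an assumed coefficient of variation between animals of 0.2, the same rule called 194 unchanged genes, and with 0.3 it called 1050; the spread between animals is unknown here.

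Genes of cardiac wall stress were higher in the knockout-labelled library. Nppa and Nppb, which encode the natriuretic peptides ANP and BNP, were at 10987 against 2868 RPM (ratio 3.83, 3.78 to 3.89) and 2468 against 585 RPM (ratio 4.22, 4.09 to 4.35). They lie side by side on chromosome 4, from 148000746 to 148002067 and from 147985789 to 147987205. The calcineurin regulator gene Rcan1 had a ratio of 3.26 (3.02 to 3.52) and the stress cytokine gene Gdf15 a ratio of 5.14 (2.68 to 10.9). Of 20 measured cardiac stress and fetal genes, 8 were at least 2-fold higher and 0 lower, and 18 had a log2 ratio above 0. The median of the list was 0.87, above all 10000 random lists of the same size and like expression. Ankrd1 and Acta1, singled out after their values were seen, were at 7625 against 2685 and 709 against 281 RPM. The fetal myosin gene Myh7, also singled out after its value was seen, went the other way at 3148 against 4164 RPM, although an opposite-strand row overlaps it.

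The list of adult cardiomyocyte genes stood apart as lower in the knockout-labelled library, by a small amount. Myh6, the main myosin heavy chain of the adult mouse heart, was at 18405 against 19313 RPM, and Tnnt2 and Myl2 had ratios of 1.08 and 0.944. The cardiac actin gene Actc1 and the thin filament gene Nebl, singled out after their values were seen, had ratios of 0.711 (0.698 to 0.724) and 0.649 (0.584 to 0.720). The median over 32 adult cardiomyocyte genes was −0.07 (−0.18 to −0.27 under the rescalings), at percentile 0.040 of random lists, and 1 member was at least 2-fold higher and 1 lower. The lower one was Kcnj2, the inward rectifier potassium channel, at 7.75 against 49.8 RPM (ratio 0.156, 0.119 to 0.201). Gja1, which encodes connexin 43, and Pln, which encodes phospholamban and is overlapped by an opposite-strand row, had ratios of 0.570 (0.548 to 0.592) and 0.595 (0.582 to 0.607). The calcium handling and ion channel list shares 10 members with the adult cardiomyocyte list and had a median of −0.34 (−0.45 to −0.53 under the rescalings), below all 10000 random lists. Of its 31 measured members, 22 had a log2 ratio below 0. At least 2-fold lower were 5 genes: Kcnj2, Casq1, Camk2a at 24.4 against 56.0 RPM, and Kcnj3 and Scn4b, which stand outside the naming rule. Hcn2, also outside the naming rule, was among the 2 genes at least 2-fold higher.

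Lysosomal genes stood higher as a group in the knockout-labelled library, mostly by less than 2-fold. Ctsl, which encodes the lysosomal protease cathepsin L (chromosome 13, 64363214 to 64370306), was at 776 against 226 RPM (ratio 3.44, 3.27 to 3.62), and the sialidase gene Neu1 had a ratio of 2.54 (2.02 to 3.22). Ctsc, which encodes cathepsin C, was lower at 11.3 against 30.1 RPM (ratio 0.375, 0.294 to 0.475). Of 42 measured lysosomal hydrolases and activators, 31 had a log2 ratio above 0 and the median was 0.33, at percentile 99.7. Among 34 genes of the lysosomal membrane and acidification, 26 had a log2 ratio above 0 and the median was 0.42, at percentile 99.96. The vacuolar proton pump subunit genes Atp6v1b2, Atp6v0a1 and Atp6v1f had ratios of 2.38 (2.14 to 2.65), 1.74 (1.57 to 1.93) and 1.73 (1.54 to 1.96), of which the Atp6v1b2 row is overlapped on the opposite strand. The medians were 0.14 to 0.22 for the hydrolases and 0.23 to 0.31 for the membrane list under the rescalings. Lamp1, the closest relative of Lamp2, was singled out after its value was seen, at 298 against 201 RPM (ratio 1.48, 1.39 to 1.58). The list of the LAMP family and chaperone-mediated autophagy had a median of 0.41 over 11 genes (0.22 to 0.30 under the rescalings), at percentile 96.0, inside the central 95% of random lists.

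Of 40 genes of the autophagy machinery, 31 had a log2 ratio above 0, with a median of 0.30 at percentile 99.1. At least 2-fold higher were Zfyve1, a marker of the membrane from which autophagosomes form, at ratio 2.15 (1.69 to 2.76), and the Atg101 gene at ratio 2.16 (1.85 to 2.53). Atg14 had a ratio of 2.03 (1.53 to 2.72) but a log2 ratio of 0.95 with the pseudocount, under the rule, while Pik3r4, a subunit of the same lipid kinase complex, was at 7.98 against 13.0 RPM. The call for this list ended when the mean replaced the median, at percentile 95.97, and its median was 0.11 to 0.19 under the rescalings. Autophagy receptors and mitophagy genes did not stand apart (median 0.25, or 0.05 to 0.14 under the rescalings, percentile 80.2, 13 of 19 above 0), although Bnip3 was at 584 against 322 RPM. Macrophage markers, whose cells are rich in lysosomes, were also higher in the knockout-labelled library. Their 18 measured members had a median of 0.65 (0.46 to 0.54 under the rescalings). The lysosomal lists share Ctss and Cd68 with the macrophage list, and 74 lysosomal genes outside it had a median of 0.34 (0.15 to 0.23 under the rescalings) at percentile 99.98.

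Genes of fatty acid use were lower in the knockout-labelled library. Pdk4, the kinase that restrains pyruvate oxidation (chromosome 6, 5483351 to 5496278), was at 580 against 2560 RPM (ratio 0.227, 0.220 to 0.234). Of 37 genes of fatty acid uptake and oxidation, 7 were at least 2-fold lower and 0 higher, and 30 had a log2 ratio below 0. The median was −0.47, below all 10000 random lists. The 7 genes include Angptl4 and Ucp3 and, outside the naming rule, Acot1, Acot2 and Cpt1a, of which Acot1 and Acot2 are near-identical and can share reads. The coactivator genes Ppargc1a and Ppargc1b, which drive mitochondrial gene programs, had ratios of 0.395 (0.341 to 0.457) and 0.467 (0.375 to 0.578). Their list, mitochondrial biogenesis and dynamics, had a median of −0.15 at percentile 0.040, with these 2 genes of 25 at least 2-fold lower. The median was −0.26 to −0.34 under the rescalings and −0.03 at percentile 1.33 after the length and GC correction.

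The listed rows of the mitochondrial genome took 26.5% of reads in the wildtype library (exact 95% interval 26.4 to 26.5) and 16.2% (16.2 to 16.3) in the knockout-labelled library. Messenger RNA rows took 23.8% and 13.9%, while the ribosomal RNA rows differed less, at 2.02% and 1.69%. All 7 measured messenger RNAs were lower, with a median of −0.70, below all 10000 random lists. The expression bins hold equal numbers of genes, so these very abundant rows were set mostly against less abundant genes. That comparison therefore adds little to the shares. The ratio was 0.576 (0.573 to 0.579) for mt-Nd2, 0.617 (0.613 to 0.622) for mt-Nd4 and 0.576 (0.573 to 0.579) for mt-Nd5. The mt-Nd6 row had a ratio of 0.499 (0.496 to 0.501), and it overlaps mt-Nd5 on the opposite strand. The other mitochondrial messenger RNA rows, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l, were listed at 0 to 15 reads in both libraries and were not used. The shares above therefore cover few or no reads of these genes. Nuclear genes of the respiratory chain did not stand apart at a median of 0.25 (0.06 to 0.14 under the rescalings) and percentile 95.5, with 65 of 78 above 0, and Ndufs6 and Cox6a2 had ratios of 1.58 and 1.22. The gene for cytochrome c, Cycs, was the 1 member at least 2-fold lower at ratio 0.334 (0.198 to 0.544), and processed copies in the genome can take its reads. The tricarboxylic acid cycle and branched-chain amino acid list had a median of −0.01 (−0.12 to −0.20 under the rescalings) at percentile 1.12, with 0 of 29 members 2-fold apart and Idh2 at ratio 0.799.

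Sugar metabolism lists did not stand apart. For glycolysis and glucose uptake the median was 0.20 (0.01 to 0.09 under the rescalings) at percentile 65.0, and 3 of 24 genes were at least 2-fold higher: the glucose transporter gene Slc2a1 at ratio 2.95 (2.46 to 3.56), Pfkp at 2.20 (1.81 to 2.69) and Gapdh at 2.34 (2.13 to 2.57). Gapdh has many processed copies, and Pfkp is overlapped on the opposite strand. For glycogen metabolism the median was 0.04 at percentile 13.5 and the mean was −0.09, so the signs differed, and the mean stood apart at percentile 0.89. At least 2-fold lower were 4 of 25 genes: the phosphorylase kinase gene Phkg1 at ratio 0.294 (0.227 to 0.378), overlapped on the opposite strand, and the glycogen-targeting phosphatase subunits Ppp1r3b, Ppp1r3d and Ppp1r3c at 0.292, 0.453 and 0.485.

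**Figure D2:**
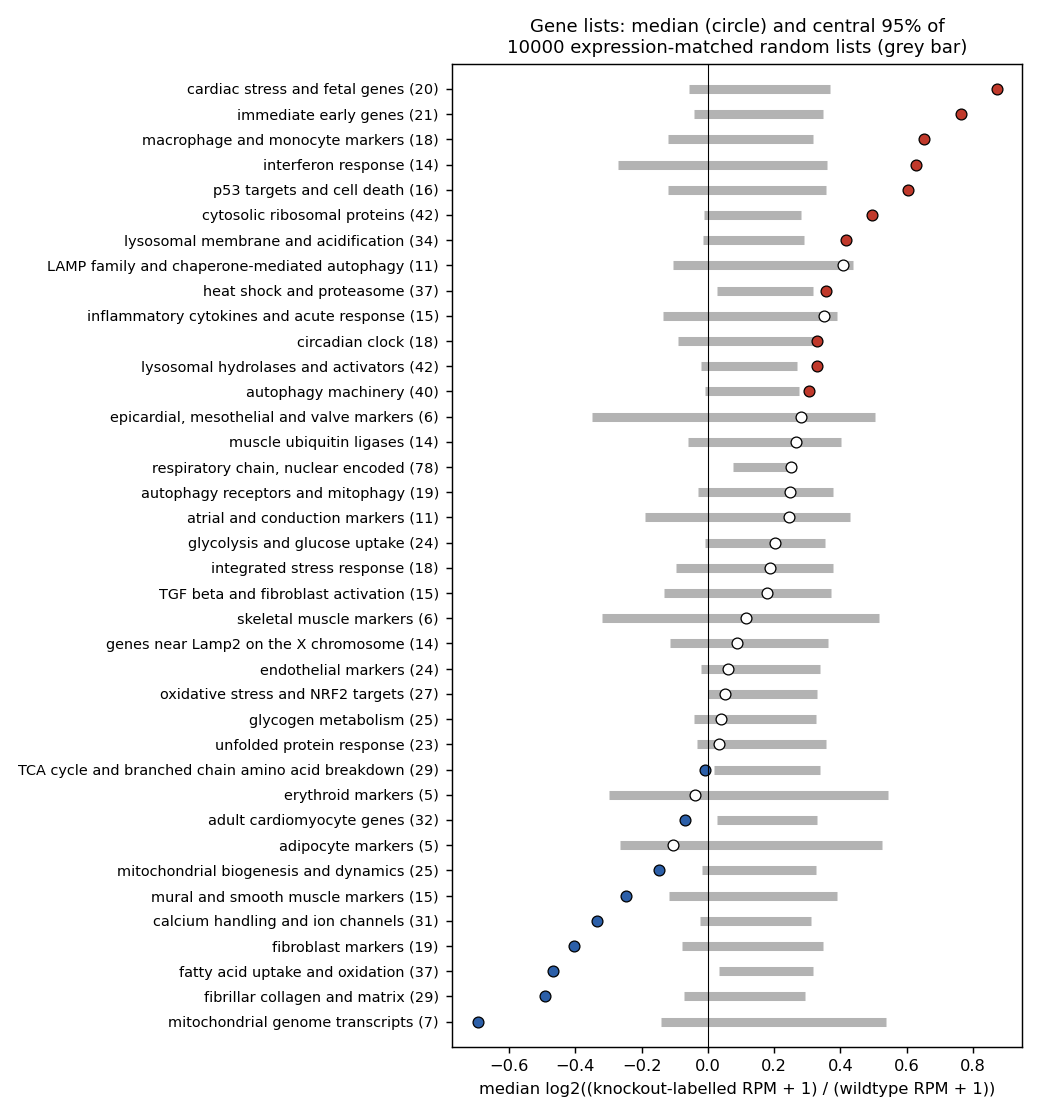
Median log2 ratio of each gene list with at least 5 measured members (circle, number of measured members in brackets) and the central 95% of medians of 10000 expression-matched random lists (grey bar); red circles lie above, blue circles below and open circles inside that range. Cardiac stress and fetal genes have the highest median at 0.87 and mitochondrial genome transcripts the lowest at −0.70.

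The lists of collagen and fibroblast genes were lower in the knockout-labelled library, though not every member. Col1a1 and Col3a1, the main fibrillar collagens, were at 6.50 against 28.5 RPM (ratio 0.228, 0.167 to 0.305) and 6.38 against 36.4 RPM (ratio 0.175, 0.130 to 0.234). Lox, the enzyme that cross-links collagen, was higher at 54.7 against 12.8 RPM (ratio 4.26, 3.45 to 5.30), as was Thbs2, which stands outside the naming rule. Of 29 genes of fibrillar collagen and matrix, 6 were at least 2-fold lower and 22 had a log2 ratio below 0, with a median of −0.49, below all 10000 random lists. Fibroblast markers, which share 5 of these genes, had a median of −0.40, below all 10000 random lists, with 5 of 19 at least 2-fold lower: Col1a1, Col3a1, Lum, Islr and, outside the naming rule, Pi16. The fall was not shared by all fibroblast markers, as 4 had a log2 ratio above 0. Dcn, Pdgfra, Gsn and Col1a2, singled out after their values were seen, had ratios of 1.04, 0.982, 0.971 and 0.724. The list of TGF beta and fibroblast activation did not stand apart (median 0.18, or 0.01 to 0.08 under the rescalings, percentile 69.0). In it Ctgf was at 2070 against 874 RPM, with an overlapping row on the opposite strand, and Wisp2 was at 1.94 against 6.66 RPM. This list was unstable: it lay at percentile 1.05 with a minimum of 1 RPM and at 99.7 with a minimum of 20 RPM.

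Markers of macrophages stood apart as higher and those of mural cells as lower in the knockout-labelled library. All 18 measured macrophage and monocyte markers had a log2 ratio above 0, with a median of 0.65 above all 10000 random lists. The 4 genes at least 2-fold higher were Gpnmb, a glycoprotein of lysosome-rich phagocytes, at 27.8 against 4.40 RPM (ratio 6.32, 4.46 to 9.19), the lectin gene Lgals3 at ratio 2.76 (1.84 to 4.23), and the complement genes C1qb and C1qa at ratios of 2.64 and 2.18. Mural and smooth muscle markers had a median of −0.25 (−0.35 to −0.43 under the rescalings) at percentile 0.19, with 12 of 15 below 0 and none 2-fold apart, and this call ended with a minimum of 20 RPM (percentile 2.63). Higd1b had a ratio of 0.545 (0.333 to 0.876). Endothelial markers had a median of 0.06 at percentile 13.8, and single members went both ways, with Sox17 at ratio 3.55 (2.89 to 4.39) and Aplnr and Sox18 at 0.179 (0.105 to 0.291) and 0.325 (0.272 to 0.386).

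The lists of p53 targets and cell death, immediate early genes and the interferon response stood apart as higher in the knockout-labelled library. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 418 against 85.0 RPM (ratio 4.92, 4.54 to 5.34). Gadd45g and the survival gene Bcl2l1 had ratios of 4.39 (3.57 to 5.44) and 3.75 (3.53 to 3.99), and the pro-death gene Bcl2l11 had a ratio of 0.452 (0.343 to 0.591). The list of p53 targets and cell death had a median of 0.60, above all 10000 random lists, with 14 of 16 above 0. Of 21 immediate early genes, 9 were at least 2-fold higher, with a median of 0.76 above all 10000 random lists. Cyr61 was at 636 against 120 RPM, and Maff, Btg2 and Atf3 had ratios of 3.74, 3.36 and 3.08. The interferon response had a median of 0.63 at percentile 99.96 (0.35 to 0.42 under the rescalings, where 13 genes were measured), and 11 of 14 genes were above 0. Irf7, Ifit3, Ifit1 and, outside the naming rule, Bst2 were at least 2-fold higher, and Gbp2 was lower. These genes were scarce, with Irf7 at 11.7 against 2.38 RPM.

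The heat shock and proteasome list had a median of 0.36 at percentile 99.4, with 36 of 37 members above 0. The small heat shock protein gene Hspb1 had a ratio of 2.53 (2.31 to 2.78) and the proteasome genes Psmb7 and Psmd11 had ratios of 1.65 and 1.62. This call ended after a correction for transcript length and GC content added after the data were seen (percentile 93.3) and with the mean (97.45), and the median was 0.16 to 0.25 under the rescalings. The unfolded protein response did not stand apart (median 0.03, percentile 10.6), except on the low side with a minimum of 20 RPM (percentile 0.37), with Pdia4 at ratio 0.583 and Edem1 at 1.68. Neither did the integrated stress response (median 0.19, percentile 66.7), the NRF2 targets (median 0.05, percentile 8.72), the muscle ubiquitin ligases (median 0.26, or 0.07 to 0.15 under the rescalings, percentile 81.3) or the inflammatory list (median 0.35, percentile 95.04). The inflammatory list did stand apart as higher with a pseudocount of 5 RPM (percentile 98.3), a minimum of 20 RPM (above all random lists) and the mean (99.85). Single members of these lists went both ways. Chac1 and Ddit4 had ratios of 4.02 and 3.40, and Mt1 and Gpx3 of 4.87 and 2.34. Cblb and Nfkbia were at ratios of 2.30 and 3.34. Lower members were Aldh1l2 at ratio 0.345, Cat at 0.556, Asb2 and Asb15 at 0.675 and 0.672, and Ccl2 at 0.120. Under the scaling without mitochondrial transcripts and the 10 most abundant genes, the positive medians of the endothelial, skeletal muscle, unfolded protein response, integrated stress response, NRF2, glycogen, inflammatory and Lamp2 neighbour lists turned negative. Those of the endothelial, unfolded protein response, NRF2, glycogen and Lamp2 neighbour lists also did so under the other rescalings. The 5 RPM minimum was applied anew after each rescaling, so a list could gain or lose members. The inflammatory list went from 15 to 16 members under the scaling without mitochondrial transcripts, and its median from 0.35 to −0.02.

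**Figure D3:**
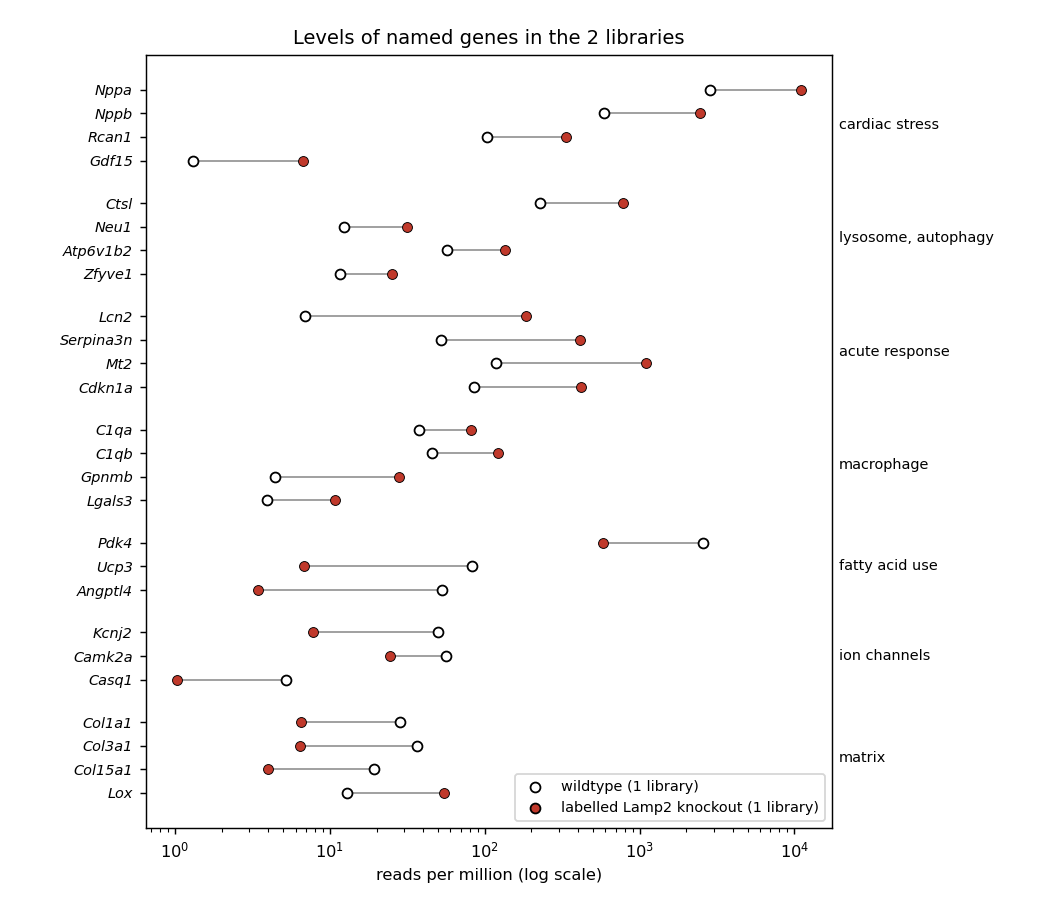
RPM (horizontal, log scale) of named genes in the wildtype library (open circles) and the library labelled Lamp2 knockout (red circles), 1 library each and therefore without error bars. Nppa stands at 10987 against 2868 RPM and Ctsl at 776 against 226 RPM, while Pdk4 stands at 580 against 2560 RPM and Col3a1 at 6.38 against 36.4 RPM.

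Of the 38 lists with at least 5 measured members, 20 stood apart from random lists, 11 on the high side and 9 on the low side, where 1.9 would be outside the range by chance if the lists were independent. They are not independent, since lists share members and genes within a list vary together. The authors' deposited table holds a fold for 13240 genes and a p-value by a method not stated in the sources used here. In the authors' deposited table, 3500 of these genes have a p-value under 0.001, of which 483 have a fold of 2 or more and 388 a fold of 0.5 or less. For Lamp2 the authors' deposited table gives a fold of 0.95 and a p-value of 0.303. These p-values compare 2 libraries and not the genotypes.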

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

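The correction for transcript length and GC content and the removal of cDNA clone rows were added after the data were seen; the other settings were planned. The counts of 342 higher and 242 lower genes became 194 and 75 with a pseudocount of 5 RPM, and 220 and 92 with a minimum of 20 RPM, where fewer genes were tested. The lower count was 397 both with a minimum of 1 RPM and with no filter, where more genes were tested. A ratio of 1.5 gave 1307 and 745, and a ratio of 3 gave 87 and 46, by construction. Scaling without mitochondrial transcripts and the 10 most abundant genes gave 214 and 394 and lowered the Lamp2 ratio from 0.955 to 0.834, since it multiplies all ratios by 1 factor. The other counts stayed within 1.5 times, including 341 and 221 after the length and GC correction, and 321 and 235 without clone rows. The binomial test of the reads left 342 and 242, which is no separate check, since the rule of size ensures it at these depths. The number of lists apart was 19 to 23 over the settings run, and 16 of the 20 lists stood apart in every one. The exceptions were autophagy machinery (95.97 with the mean), mural markers (2.63 with a minimum of 20 RPM), heat shock and proteasome (97.45 and 93.3) and circadian clock (94.9 with a pseudocount of 5 RPM, 97.1 with 10 bins, 90.4 with the mean); the cause was not tested. Of 413 list percentiles, 393 kept their side of the range, 7 left the outer range and 13 entered it. Of 930 values of named genes, 195 moved beyond their counting interval and 0 of the called ones changed sign. Depth limits genes of few reads; the absence of replicates limits all results.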

Other observations

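The tests of neutrophils and of macrophages, the length and GC correction, the 3 added gene lists and the difference between FOXO and PPAR targets were chosen only after the results were seen, as were the 3 patterns weighed here. The technical lists and the remaining cell type lists were fixed before the data were examined. Cytosolic ribosomal protein genes had a median log2 ratio of 0.49, above all 10000 random lists, with 38 of 42 above 0 (median 0.30 to 0.38 under the rescalings). Rplp1 and Rps9 were at 858 against 600 and 712 against 537 RPM in the knockout-labelled and wildtype libraries, and processed pseudogenes can share the reads of such genes. Of 18 circadian clock genes, 4 were at least 2-fold higher, with a median of 0.33 at percentile 97.8, a call that ended with a pseudocount of 5 RPM (94.9), with 10 expression bins (97.1) and with the mean (90.4), and a median that was 0.15 to 0.23 under the rescalings. They included Per1 at ratio 2.11 (1.96 to 2.28), Per2 at 2.29 (1.76 to 3.00) and Nfil3 at 2.70 (2.16 to 3.39). Bhlhe41, outside the naming rule, was the 1 gene at least 2-fold lower. Short transcripts had higher log2 ratios than long ones, with medians of 0.24 in the shortest and 0.03 in the longest of 5 equal groups, and the median of nuclear respiratory chain genes was 0.25 before and 0.09 after the length and GC correction.

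The remaining cell type lists did not stand apart in the settings fixed for the report. The medians were −0.04 for erythroid markers (percentile 21.02), 0.28 for epicardial, mesothelial and valve markers (81.5), 0.24 for atrial and conduction markers (79.2) and 0.12 for skeletal muscle markers (48.6). Under the rescalings they were −0.14 to −0.21, 0.02 to 0.10, 0.05 to 0.13 and −0.07 to 0.01. Adipocyte markers had a median of −0.10 (11.7; −0.22 to −0.30 under the rescalings) and a mean of 0.03, and the signs differed; they stood apart as lower with a minimum of 1 RPM (percentile 0), with no filter (0.31) and after the length and GC correction (1.74). The atrial list went both ways, at percentile 1.63 with a minimum of 1 RPM, 0.38 with no filter and 98.1 after that correction. Among adipocyte markers, the glycerol channel gene Aqp7 had a ratio of 0.264 (0.221 to 0.315) and Thrsp, a lipogenic gene, a ratio of 2.81 (2.29 to 3.48). Among atrial markers, Gja5, which encodes connexin 40, was at 1.48 against 7.13 RPM and Clu, a secreted chaperone, at 1536 against 618 RPM. Lists of lymphocytes and granulocytes, Schwann cells and neurons, the cell cycle and histones had fewer than 5 measured members, and Pcna, a replication factor, had a ratio of 1.02 (0.855 to 1.22).

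PPAR target genes were lower in the knockout-labelled library, with a median log2 ratio of −0.57 over 33 genes, 30 of them below 0, and −0.66 over the 9 outside the fatty acid list. Length and GC content as the whole cause is argued against, since the correction kept 1.06 of the shift (bootstrap range over genes 0.857 to 1.24). FOXO targets, which fasting induces along with PPAR targets, did not share the fall of the PPAR targets as a list. This does not decide on feeding state. Glucocorticoid exposure, which remains open below, may raise FOXO targets and hide a fall. The 25 FOXO targets outside the fatty acid lists had a median of 0.42 (bootstrap range over genes 0.132 to 0.857). Under the rescalings it was 0.22 to 0.31, with the range reaching −0.06 in 1 of them. It lay 0.99 above the PPAR median (bootstrap range 0.67 to 1.60). The difference was 0.95 (0.59 to 1.51) without the 3 genes shared with the glucocorticoid list. The 22 genes left had a median of 0.19 to 0.27 under the rescalings, with ranges reaching below 0 in all 3. A rise of their own is therefore not established, and glucocorticoids may act on others of them. FOXO targets among the fatty acid genes, which were lower as a list, were left out. Of the 25, 3 are also in the autophagy machinery list. The hour of harvest cannot be told apart from genotype, because evening clock genes had a median of 0.05 with 5 above and 5 below 0 and morning clock genes 0.28; their difference of −0.23 met a preset bound against this explanation, but members going both ways decide nothing. The labelled genotype stays open and untested, as genotype and animal cannot be separated with 1 mouse each.

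Lcn2, Serpina3n, Mt2 and Cdkn1a, single genes from 3 lists that respond to acute stress, were higher in the knockout-labelled library, while the inflammatory and acute response list did not stand apart as a whole (percentile 95.04). Neutrophils as the source of Lcn2 are argued against: S100a8 and S100a9, their most abundant transcripts, had 6 and 88 reads against 1613 for Lcn2, a ratio of 0.0583 (0.0468 to 0.0718). Glucocorticoid exposure remains open, and 31 other glucocorticoid targets went with it, at a median of 0.61 (0.43 to 0.51 under the rescalings) and percentile 100. The 23 in no other list also lay at percentile 100, with a median of 0.61. Under the rescalings the median of these 23 was 0.42 to 0.49, with bootstrap ranges over genes reaching below 0 in all 3. Pdk4 and Angptl4, also known targets, went the other way. Handling at harvest also remains open, as Fos, Egr1, Junb and Nr4a1 had a median of 0.91 (0.72 to 0.80 under the rescalings), with Nr4a1 alone lower at −0.51. Bootstrap ranges over these 4 genes reached below 0 in all 3 rescalings. All 4 are in the immediate early list that stood apart as higher, so their median is no separate support. The labelled genotype stays open too and was not tested apart from glucocorticoid exposure and handling.

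The 2 lysosomal lists and the autophagy machinery list stood apart as higher in the knockout-labelled library. The call for autophagy machinery ended with the mean (percentile 95.97), and autophagy receptors and mitophagy genes did not stand apart (percentile 80.2). Length and GC content as the whole cause is argued against, since 3 of the 3 lists still stood apart after the correction. More macrophages in the tissue may contribute: the 18 macrophage markers gained 272 RPM in sum and the 74 lysosomal genes outside that list, with a median of 0.34 (0.15 to 0.23 under the rescalings), 1837 RPM, a ratio of 0.148. Without a macrophage expression profile, no bound can be set on that share, and the 2 sources cannot be told apart. The labelled genotype stays open and untested with 1 mouse each.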
